A study of Mus musculus with 6 samples.

How the data were processed

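RNA from 6 samples of 1 mouse leukaemia cell line was profiled, 3 treated with vehicle and 3 with DB2313 at 330 nM for 24 h. Per the labels' protocols, total RNA was extracted with a silica column kit, labelled with biotin using a whole-transcript terminal labelling kit from Affymetrix, and hybridised to Affymetrix arrays. Per the submitters' processing notes, Affymetrix Expression Console was used, with no version given. The background correction and the method that summarised probes into probe sets are not given in the sources used here. The deposited table holds 1 value per probe set and array on the log2 scale, as judged from its range and quartiles. The 6 arrays had nearly equal quartiles, so they had probably been brought to a common distribution before deposit, as judged from these values alone. Scanner files were not used here, so the background of each probe set and the scan batches could not be examined. Signals near the lower end of the scale can understate a fold change, and a large overall shift in RNA content would not be visible after such normalization.

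The table has 41345 rows. In the platform annotation 23521 rows had 1 gene symbol and 1814 had several, and 16010 rows had no entry and are unnamed here. For 23328 of the rows with 1 symbol, the gene identifier was found in the RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed updating. Rows with several symbols or none stayed out of the tests. For the 1082 genes with several rows, the row with the highest mean over all 6 arrays was kept, which left 22180 genes. Among genes past the threshold, 27 had other rows, and 24 of these 29 rows had the same sign as the row kept. The genome build behind the probe sets is not given, so no coordinates are printed, and the RefSeq table served only for names, gene lengths and the order of neighbouring genes.

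DB2313 was compared with vehicle using limma 3.58.1 in R 4.3.3, with lmFit and eBayes on the deposited log2 values, 2-sided, and Benjamini-Hochberg adjustment over all genes at 0.05. No minimum fold was set. The prior had 3.61 degrees of freedom and an SD of 0.0972. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 31 lists. Beside it stand camera with an estimated correlation, fry, and the count of members past 0.05 when adjusted over the list alone. The 31 lists hold 1008 distinct genes, of which 892 were measured. They cover PU.1 targets and ETS factors, the fate factors of myeloid and stem cells, marker genes of myeloid, lymphoid, erythroid, megakaryocytic, mast, dendritic and stromal cells, and receptor, inflammation, cell cycle, stress, growth and metabolism genes. The number of arrays limits the precision, and confidence intervals are at 95%.

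The groups, the test, the lists, the alternatives and the rule for named genes were set before the data were examined. The rule names Spi1, Csf1r, Junb and E2f1 whatever their values. It adds the 12 genes with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap, leaving out predicted genes, unnamed clones, microRNAs, small nucleolar RNAs and olfactory or vomeronasal receptors. From each list it takes up to 4 members past the threshold with the largest absolute change or, where none passes, the 2 with the smallest p. Genes named outside the rule are said to be so. The fallback of the rule for fewer than 10 genes in a direction was not needed.

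The gene test was tested on simulated data for 22180 genes with 200 changed, in 10 simulations of 3 against 3 arrays. It recovered 52.7% of genes changed by a log2 fold change of 0.5, 96.3% at 1 and 99.7% at 2, and 4.72% of the genes called were false. The simulated genes were independent, with variances drawn from the prior that limma fitted. A false share near the threshold follows from that setting and is not an estimate for the real data. The list test recovered 100% of lists of 40 genes shifted by -0.15 under both correlations, with 0% false calls, on simulated genes that were independent of one another. Every member of a shifted list moved by the same amount, whereas members of the real lists went both ways. The recovery is therefore not an estimate for the real lists. Alternatives were filters that leave out genes below the 0.25 quantile or below the median of signal, quantile normalization, median centring, an offset of 32 on the linear scale, a trended and robust prior, the replicate number as a block, the mean of all rows of a gene, each array left out in turn, all rows tested, a minimum fold of 1.5 and an unmoderated test per gene.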

Results

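Gene expression was measured on Affymetrix arrays in a mouse acute myeloid leukaemia cell line with low levels of PU.1, the ETS transcription factor encoded by Spi1. The line came from a leukaemic mouse that lacked the upstream regulatory element (URE), an enhancer of Spi1. Cells received DB2313, a small molecule described as a PU.1 inhibitor, at 330 nM, or the same volume of water as vehicle, and RNA was collected after 24 h. Each group had 3 arrays, named in the labels as biological replicates. Whether these came from separately started cultures is not stated, so the p-values measure the spread between these samples. The median signal per array lay between 4.77 and 4.82 on the log2 scale, and 22180 genes were tested. Pearson's r across genes was 0.996 for every pair of arrays of 1 group and lay between 0.994 and 0.995 for pairs across groups. The first principal component held 37.2% of the variance and separated the groups.

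The comparison asked which transcripts differed after 24 h of the PU.1 inhibitor. The strongest rise was that of Serpinb9e, a member of a family of intracellular serine protease inhibitors, which went from 2.81 ± 0.09 to 9.32 ± 0.12 (log2, SD, n = 3), a log2 difference of 6.51, or 4.10 with an offset of 32 on the linear scale that damps dim genes. No fold is given for it, since the vehicle signal lay near the lower end of the scale and background was not measured. Ptprn, which encodes a membrane protein of secretory granules, was 11.2-fold higher. The steepest falls were those of Xdh, the purine catabolic enzyme xanthine dehydrogenase (5.65-fold lower), and of Ly96, the co-receptor through which the lipopolysaccharide receptor binds its ligand (4.59-fold lower). Pparg, a nuclear receptor of lipid metabolism, was 3.83-fold lower, and C5ar1, a receptor for a complement fragment, 3.77-fold lower. In all, 401 genes passed an adjusted p of 0.05 in limma, of which 226 were higher and 175 lower with DB2313. At least a 2-fold difference was reached by 19 of the higher and 16 of the lower genes, and the median absolute log2 fold change of the 401 genes was 0.53. Without adjustment, 2810 genes had a p under 0.05, 1443 of them higher. The values of the 3 DB2313 arrays lay entirely above or below those of the 3 vehicle arrays for all 401 genes, and for 19.3% of all genes tested, where chance gives 10%. The number of genes past the threshold fell to between 136 and 187 when any 1 array was left out, the lowest without DB2313 replicate 3. With the offset of 32 the log2 fold changes were -1.61 for Xdh, -1.11 for Pparg and -1.10 for C5ar1, against -2.50, -1.94 and -1.91, and these and Serpinb9e stayed past the threshold.

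Among the 12 genes with the largest rise, Kcnq3, a voltage-gated potassium channel subunit, had a log2 fold change of 1.93 (SE 0.089, adjusted p = 0.000232). B3gnt5, a glycosyltransferase of glycolipid synthesis, followed with 1.66 (SE 0.121, adjusted p = 0.00122). The anion exchanger Slc26a6 and C2cd4a each rose by 1.43 on the log2 scale. Tle4, a transcriptional corepressor, rose by 1.25, and Lox, the collagen cross-linking enzyme lysyl oxidase, by 1.18. The remaining 4 were Atp13a4 (1.16), Napepld, a phospholipase that releases N-acylethanolamines (1.14), the lipase gene Lipn (1.14), and Taf9b (1.10). Their vehicle signals differed widely, from 2.81 for Serpinb9e to 7.50 for Kcnq3. The adjusted p for Serpinb9e was 5.57e-08 (SE 0.084) and that for Ptprn 6.20e-05 (SE 0.130). Serpinb9e belongs to a family of similar neighbouring genes, and the probe sets were not checked here for sequence shared with its relatives. Without vehicle replicate 1, Atp13a4 did not pass (adjusted p = 0.0530), and with an offset of 32 Lox had 0.61 and Atp13a4 0.58.

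Several of the 12 genes with the largest fall encode proteins of the myeloid cell surface. Besides Ly96 and C5ar1, these were Cd33, a sialic acid-binding lectin (log2 fold change -1.85), the C-type lectin receptor Clec5a (-1.62) and Ptafr, the receptor for platelet-activating factor (-1.56). Clec5a was the brightest of the 12, at 10.47 ± 0.06 in vehicle and 8.85 ± 0.15 with DB2313 (log2, SD, n = 3). Secreted proteins among them were Hgf, the hepatocyte growth factor (-1.65), and Prg4, the joint lubricant lubricin (-1.64). The adhesion molecule gene Clmp had -1.76 in its brighter row but -0.11 in its other row and -0.93 as the mean of rows, and Slfn2, a Schlafen family gene, had -1.63. Me1, the cytosolic malic enzyme that supplies NADPH, had -1.46 (SE 0.095, adjusted p = 0.000755). For Xdh, the log2 fold change was -2.50 (SE 0.075, adjusted p = 1.81e-05), and for Pparg -1.94 (SE 0.108, adjusted p = 0.000449). Without DB2313 replicate 3, Prg4 did not pass (adjusted p = 0.0531), and with an offset of 32 Clmp had -1.13, Prg4 -0.88 and Slfn2 -1.01.

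**Figure D1:**
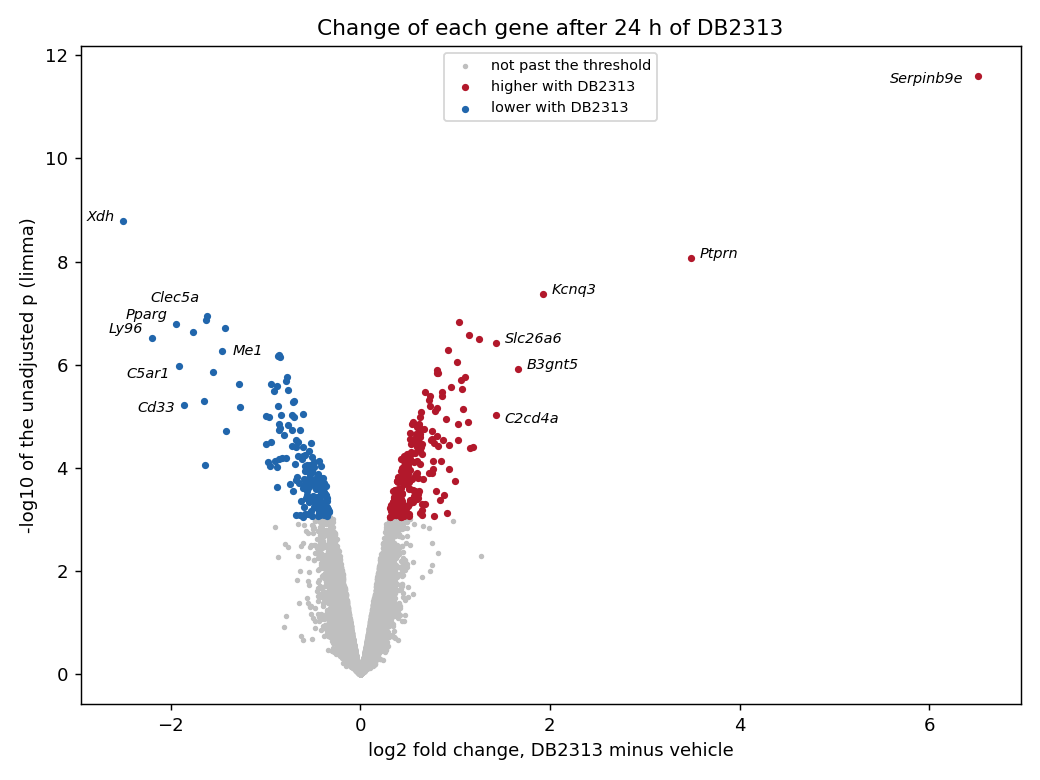
Each point is 1 of the 22180 genes tested, placed by its log2 fold change (DB2313 minus vehicle, horizontal axis) and the negative log10 of its unadjusted limma p (vertical axis). Red and blue points passed an adjusted p of 0.05, 226 higher and 175 lower, and Serpinb9e stands apart at 6.51.

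**Figure D2:**
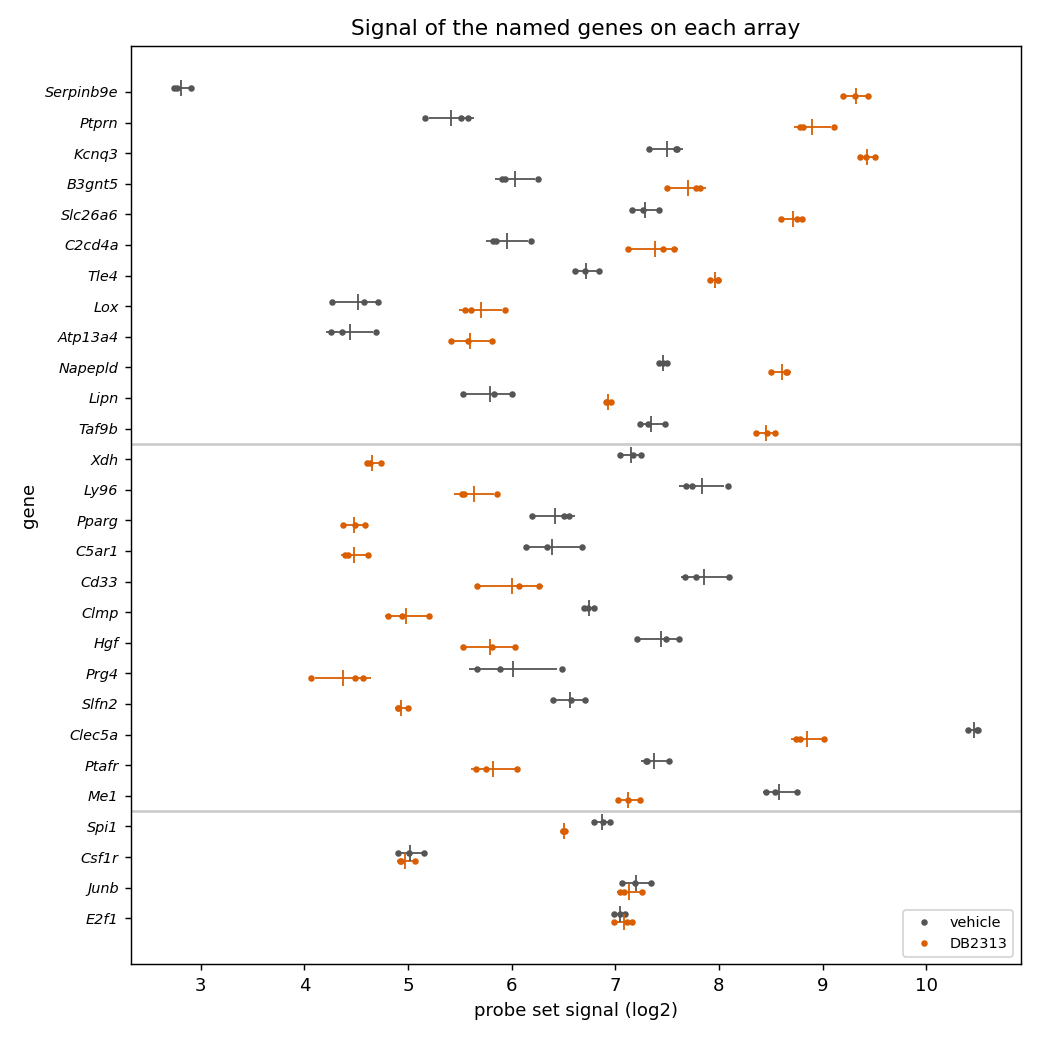
Log2 signal (horizontal axis) on each of the 3 vehicle (grey) and 3 DB2313 (orange) arrays for the 12 genes with the largest rise (top block), the 12 with the largest fall (middle block), and Spi1, Csf1r, Junb and E2f1 (bottom block). Dots are arrays, vertical ticks are means and horizontal bars are 1 SD; in the 24 genes of the upper blocks the groups do not overlap, and in Csf1r, Junb and E2f1 they do.

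The gene of the inhibited factor and 3 PU.1 target genes often used as readouts were examined whatever their values. Spi1 itself was 1.29-fold lower with DB2313, at 6.87 ± 0.08 in vehicle and 6.50 ± 0.01 after treatment (log2, SD, n = 3), with a log2 fold change of -0.37 (SE 0.064, adjusted p = 0.0342). Csf1r, the receptor of macrophage colony-stimulating factor, did not pass, with a log2 fold change of -0.05 and a 95% confidence interval from -0.24 to 0.14 (adjusted p = 0.867). Its vehicle signal, 5.02, lay below the median of all genes, 5.17, and the filter at the median left it out. Junb, a member of the AP-1 family, had -0.07 (interval -0.29 to 0.15, adjusted p = 0.836). E2f1, a transcription factor of the cell cycle, had 0.04 (interval -0.12 to 0.21, adjusted p = 0.858). The call for Spi1 was lost when any 1 array was left out, with adjusted p between 0.0648 and 0.134. Among 23 measured ETS family genes, Spi1 alone passed over all genes tested, and 1 higher and 1 lower passed when adjusted over the list alone (camera adjusted p = 0.442).

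Genes with well-described direct PU.1 regulation in myeloid cells were lower as a group with the preset correlation of camera (adjusted p = 0.0336), and did not pass with an estimated correlation (adjusted p = 0.306). Their mean log2 fold change was -0.11 and their median -0.05, with 25 of 41 below 0. Of the 41 measured members, 5 fell, 1 rose and 35 did not pass; adjusted over the list alone, 8 were lower and 1 higher. Clec5a had the largest change, followed by Itgb2, the common leukocyte integrin beta chain (log2 fold change -0.70), and Ncf1, a cytosolic subunit of the phagocyte NADPH oxidase (-0.68). Cybb, the membrane subunit of the same oxidase, rose by 0.65. Spi1 and Cd53, a tetraspanin (-0.49, chosen after its values were seen), complete the 5. Ncf1 and Cybb had adjusted p of 0.0472 and 0.0468 and did not pass after quantile normalization (0.0504 and 0.0534); Ncf1 was also lost when any 1 array was left out (0.0618 to 0.157), Cybb in 5 of these 6 settings (up to 0.154), Itgb2 in 5 (up to 0.0966) and Cd53 in 4 (up to 0.0574). Cd53 did not pass under the replicate block either (adjusted p = 0.0656), nor did Cybb or Spi1. Without vehicle replicate 2 the list did not pass (adjusted p = 0.0751).

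Receptors of innate immunity had the lowest mean log2 fold change of the 31 lists (-0.17), carried by a few members, since the median was -0.009 with 24 members below 0 and 20 above. Among 44 measured Toll-like, Fc, C-type lectin and paired immunoglobulin-like receptors, 6 fell and 1 rose; adjusted over the list alone, 7 were lower and 1 higher. Ly96, Cd33 and Clec5a led, and Tlr7, an endosomal sensor of single-stranded RNA, had a log2 fold change of -0.88. Chosen after their values were seen, the inhibitory receptors Lilrb4a (-0.70) and Cd300a (-0.60) also fell, and Clec7a, the beta-glucan receptor, rose by 0.81. The list passed with a camera adjusted p of 0.0361, against an adjusted p of 0.312 with an estimated correlation. Of 43 monocyte and macrophage markers, 2 fell, Fn1, encoding fibronectin (-1.27), and Lgals3, encoding galectin (-0.90), and none rose; adjusted over the list alone, 4 were lower and 1 higher. The camera adjusted p of that list was 0.0336, and its adjusted p was 0.306 with an estimated correlation. The receptor list did not pass without vehicle replicate 1 (adjusted p = 0.0504), vehicle replicate 3 (adjusted p = 0.127) or DB2313 replicate 1 (adjusted p = 0.108), nor the macrophage list without vehicle replicate 2 (adjusted p = 0.0751) or DB2313 replicate 1 (adjusted p = 0.0573); Tlr7, Lgals3 and Cd300a lost their calls in 4, 2 and 2 of the 6 settings with 1 array left out (adjusted p up to 0.0691, 0.0602 and 0.0537). With an offset of 32, Tlr7 had -0.56. Lilrb4a and Cd33 belong to families of similar genes, for which short probes can be shared.

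Members of a list named for granule proteins of neutrophils and their precursors went both ways. Not all of them encode granule proteins, as Ncf1 encodes a cytosolic subunit. Of 42 measured, Cybb and Anxa1, encoding annexin A1 (0.63), rose, and Ncf1, S100a8, encoding a calprotectin subunit (-0.63), and, chosen after their values were seen, Mgst1 (-0.59) and Hp (-0.39) fell. Adjusted over the list alone, 2 were higher and 5 lower; the list did not pass (camera adjusted p = 0.442), with a mean below 0 and a median above it. Named outside the rule, the granule enzyme genes Elane (-0.0016) and Mpo (0.29) did not pass (limma adjusted p = 0.994 and 0.281). The vehicle signal of Elane, 13.05, lay near the top of the scale. Among 33 integrins, selectins and chemokine receptors, C5ar1, Itgb2, Ccr1, a chemokine receptor (-0.95), and Cd44, the hyaluronan receptor (-0.52), fell and none rose. Adjusted over the list alone, 4 were lower and 1 higher (camera adjusted p = 0.111). Of 41 inflammatory and NF-kB target genes, the inflammasome sensor Nlrp3 (-1.41), Socs3, a feedback inhibitor of cytokine signalling (-0.56), and the interleukin antagonist Il1rn (-0.41) fell, and Olr1, a scavenger receptor, rose by 0.73. That list had 6 lower and 2 higher members adjusted over the list alone, and a camera adjusted p of 0.0581, and passed without vehicle replicate 1 (0.0371) or DB2313 replicate 2 (0.0341), against 0.462 with an estimated correlation on all arrays. Of 36 cytokine receptor and signal genes, Il6ra (-0.41) and Socs3 fell and Il1r1 rose by 0.44; the same counts held adjusted over the list alone (camera adjusted p = 0.0704, 0.0236 without vehicle replicate 3, and 0.462 with an estimated correlation). S100a8, Socs3, Il1rn, Il1r1 and Il6ra did not pass when any 1 array was left out (adjusted p from 0.0512 to 0.164), and Anxa1, Ccr1 and Cd44 did not in 3, 3 and 5 of the 6 such settings. Hp did not pass in any of the 6 (adjusted p up to 0.108) nor under the replicate block (0.106), and Mgst1 did not in 2 of the 6 (up to 0.0532). With an offset of 32, Nlrp3 had -0.76, Il1rn -0.22 and Ccr1 -0.34.

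Genes of ribosome biogenesis and MYC targets were lower as a group by small amounts with the preset correlation (camera adjusted p = 0.00405), and did not pass with an estimated correlation (adjusted p = 0.312). Of 39 measured, 34 had a log2 fold change below 0 and the mean was -0.08, while only Tfrc, the transferrin receptor (-0.72), and Rrp1b, a ribosomal RNA processing factor (-0.37), passed, also when adjusted over the list alone. Genes of the unfolded protein and integrated stress responses had the same mean, -0.08, with 28 of 37 below 0. The transcription factor Atf5 (-0.60) and the amino acid transporter Slc7a5 (-0.35) fell, and 3 were lower adjusted over the list alone. That list had a camera adjusted p of 0.0194, an adjusted p of 0.306 with an estimated correlation, and did not pass without vehicle replicate 2 (adjusted p = 0.0751). Calls for Rrp1b and Slc7a5 were lost when any 1 array was left out (adjusted p from 0.0708 to 0.125).

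Few cell cycle genes passed the test. None of 51 genes of S phase entry and DNA replication passed, also when adjusted over the list alone (camera adjusted p = 0.703); the smallest p was that of E2f8, with a log2 fold change of -0.32, then Brip1 (-0.20). Among 48 genes of G2 and mitosis, the kinesin gene Kif20a (-0.37) and Ect2, needed for cytokinesis (-0.33), fell, with 3 lower adjusted over the list alone (camera adjusted p = 0.0916, 0.0165 without DB2313 replicate 3, and 0.685 with an estimated correlation). None of 18 replication-dependent histone genes passed over all genes or adjusted over the list alone (camera adjusted p = 0.0765, 0.000932 without vehicle replicate 3, and 0.631 with an estimated correlation). H1f2 had -0.21, and H2bc1, among the dimmest genes with a vehicle signal of 2.36, had -0.32, or -0.04 with an offset of 32. Of 34 p53 target and apoptosis genes, Pmaip1, encoding the pro-apoptotic protein NOXA (0.66), and Apaf1, the apoptosome scaffold (0.36), rose and none fell; adjusted over the list alone, 3 were higher and 3 lower (camera adjusted p = 0.779). Kif20a, Ect2 and Apaf1 did not pass when any 1 array was left out (adjusted p from 0.0669 to 0.160), and Pmaip1 did not in 4 of these 6 settings (up to 0.0850).

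Among regulators and markers of immature cells, the repressor Gfi1 rose from 10.25 ± 0.02 to 10.79 ± 0.01 (log2, SD, n = 3), and Myb, a factor of progenitor proliferation, rose by 0.34. No other of the 41 measured factors of myeloid and stem cell fate passed, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.627). Of 26 stem and early progenitor markers, Cd93 rose by 0.52 and Prom1 had -0.45; adjusted over the list alone 1 was higher and 2 lower (camera adjusted p = 0.329). Myb and Prom1 lost their calls when any 1 array was left out (adjusted p from 0.0585 to 0.143), and Cd93 in 5 of these 6 settings (up to 0.121). With an offset of 32, Prom1 had -0.26.

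Markers of other lineages gave few changes. Megakaryocyte and platelet genes were lower as a group with the preset correlation, with 22 of 25 below 0, though only Thbs1, encoding the matrix protein thrombospondin, passed over all genes (-0.87) and 4 were lower adjusted over the list alone. The camera adjusted p was 0.0194 and the adjusted p was 0.312 with an estimated correlation; the list did not pass without vehicle replicate 3 (adjusted p = 0.0609) or with genes below the median signal left out (adjusted p = 0.0933, 9 of the 25 remaining). Of 22 erythroid genes, Tfrc fell, and 1 higher and 1 lower passed adjusted over the list alone (camera adjusted p = 0.170). Of 18 B lymphoid markers, Cd24a rose by 0.91 and Igll1, part of the surrogate light chain, by 0.52, both also adjusted over the list alone (camera adjusted p = 0.170). With genes below the median signal left out that list passed (adjusted p = 0.00138), but only 3 of the 18 markers remained and its mean log2 fold change went from 0.11 to 0.64; with an estimated correlation on all genes the adjusted p was 0.502. Cdh5, an endothelial cadherin, rose by 0.86 as the single gene past the threshold among 21 fibroblast and stromal markers, under both adjustments including adjusted over the list alone (camera adjusted p = 0.975); this list's mean lay above 0 and its camera direction was down. None passed, also adjusted over the list alone, among 26 MHC class II and dendritic cell genes (Itgax -0.25, Bst2 0.15, camera adjusted p = 0.329). The same held for 34 mast cell, basophil and eosinophil genes (Mcpt8 0.28, Csf2rb2 -0.40, camera adjusted p = 0.779). It held also for 22 T and NK cell markers (Zap70 -0.22, Il2rb -0.13, camera adjusted p = 0.101, 0.0460 without DB2313 replicate 1, and 0.502 with an estimated correlation). With an offset of 32 the dim genes Csf2rb2, Itgax, Zap70 and Il2rb had -0.12, -0.11, -0.10 and -0.06.

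None of the metabolic, stress and signalling lists that follow passed, and at most 2 genes of each did. Me1 was the 1 gene that fell among 23 antioxidant genes, and the 1 lower adjusted over the list alone (camera adjusted p = 0.329). Pgam1, a glycolytic mutase, fell (-0.41) among 31 glycolysis and hypoxia genes, again the 1 lower adjusted over the list alone (camera adjusted p = 0.111). That list passed without vehicle replicate 1 (adjusted p = 0.0154) or DB2313 replicate 2 (adjusted p = 0.00323), while on all arrays its estimated correlation was 0.590, far above the preset 0.01, with an adjusted p of 0.843. Of 26 sterol genes, the reductase Tm7sf2 rose by 0.65 and the synthase Hmgcs1 had -0.37, with 1 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.989, with mean above 0 and median below). Fosl2, an AP-1 factor, had -0.91 among 33 immediate-early genes, of which 2 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.941). No lysosomal gene passed over all genes among 32 (Npc1 0.29, or 0.17 as the mean of rows, and Ctsb 0.28), and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.779). Of 37 interferon-stimulated genes none passed over all genes, and 4 were higher adjusted over the list alone, Gbp5 (0.98, or 0.38 with an offset of 32), Gbp3 (0.36) and, chosen after their values were seen, Iigp1 (0.35) and Igtp (0.25) (camera adjusted p = 0.329). None of 36 respiratory chain genes (Ndufb3 0.44, Uqcrc1 0.26, camera adjusted p = 0.329) or 19 heat shock genes (Hspd1 -0.16, Ahsa1 0.16, camera adjusted p = 0.111) passed, also adjusted over the list alone. Pgam1 and Hmgcs1 did not pass when any 1 array was left out (adjusted p from 0.0590 to 0.159).

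**Figure D3:**
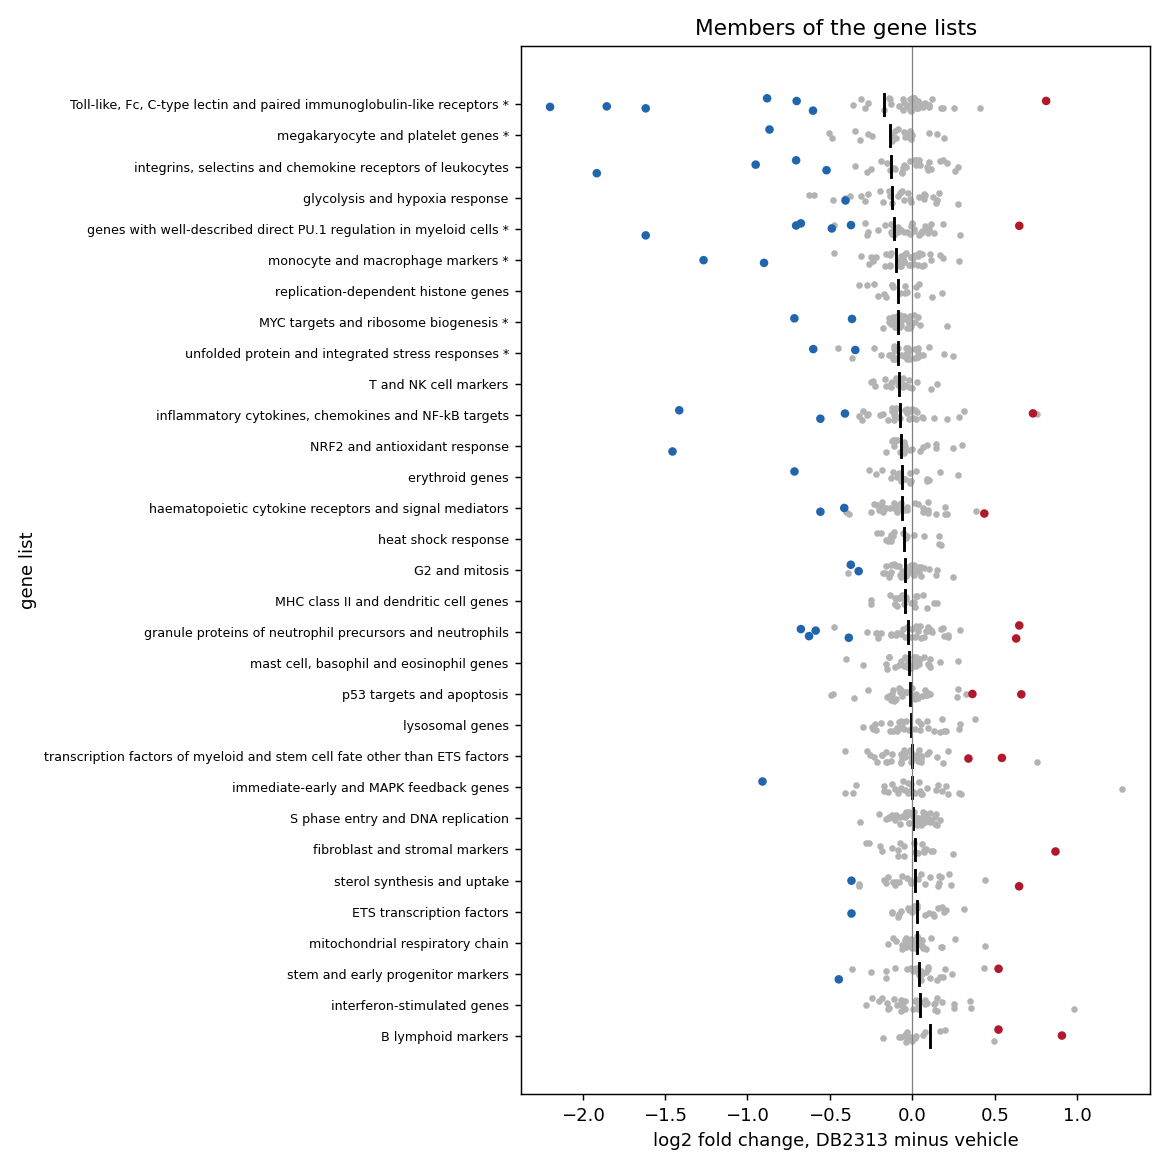
Log2 fold change (DB2313 minus vehicle, horizontal axis) of every measured member of the 31 gene lists (vertical axis), with red and blue points past an adjusted p of 0.05 over all genes and grey points not past it. Black bars are list means and asterisks mark the 6 lists with a camera adjusted p under 0.05 at the preset correlation, all of them lower with DB2313.

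Across the 31 lists, 6 passed camera with the preset correlation, and 0 did with a correlation estimated from these arrays. The smallest adjusted p was then 0.306. Among the 6, the estimated correlation was -0.015 for PU.1 targets, -0.0008 for macrophage markers, -0.0024 for stress responses and 0.0087 for receptors. These lie below the preset 0.01, so a higher correlation among members does not account for the loss of these lists. It was above the preset for megakaryocyte (0.032) and ribosome biogenesis genes (0.053). By fry, which asks whether the genes of a list move on balance 1 way without comparing them with other genes, 5 lists passed, and 26 passed its test for changes in either direction.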

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

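The alternatives were all planned, none being chosen after the results were seen. Against 401 genes changed (226 higher, 175 lower), 799 passed with genes below the median signal left out (436 and 363, fewer genes being tested), 830 with an offset of 32 (467 and 363), and 920 with a trended and robust prior (496 and 424, with 399 of the 401 shared). A minimum fold of 1.5 left 166 (89 and 77), and testing all rows of the table gave 142 (83 and 59). The unmoderated test per gene, which estimates each variance from 4 degrees of freedom, gave 70 (42 and 28), with 2758 genes at an unadjusted p under 0.05. Leaving out 1 array gave 136 to 187 genes, 72 to 108 higher and 63 to 85 lower, from fewer samples; 136 passed without DB2313 replicate 3, 142 without vehicle replicate 1, 162 without DB2313 replicate 1, 176 without DB2313 replicate 2, 185 without vehicle replicate 2 and 187 without vehicle replicate 3. For the counts where no construction is named here, the cause was not tested. With genes below the 0.25 quantile left out, quantile normalization, median centring or the mean of rows, the count stayed within 1.5 times of 401.

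The deviations of same-numbered arrays from their group means had correlations of 0.023, 0.078 and 0.0083 across genes. Arrays with different numbers had -0.071 to 0.047, so the correlations were small, though 0.078 was the highest. The labels state no pairing, and the numbers were not taken to pair the samples. With the replicate block, 190 genes passed (98 higher, 92 lower), 178 of them among the 401, and 6 lists, 5 of them among the 6 without it; the receptor list did not pass. Of the 61 named genes past the threshold, 19 did not pass under the replicate block, Spi1 among them. For Spi1 the adjusted p was 0.113 under the replicate block, which cannot move the log2 fold change of -0.37 in this balanced design. Its log2 fold change lay between -0.41 and -0.34 with 1 array left out and had an adjusted p between 0.00697 and 0.134 over the alternatives run gene by gene. Csf1r lay between -0.11 and 0.02, Junb between -0.14 and 0.01 and E2f1 between 0.01 and 0.09, and none of them passed under the alternatives run gene by gene.

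Of the 82 named genes, 61 passed, 33 of these under each of the 14 alternatives run gene by gene, and 0 of the 61 changed sign in these; Csf1r and Junb, which did not pass, did so without vehicle replicate 2. Testing all rows, the minimum fold and the unmoderated test were run for counts alone. Of the 24 genes with the largest changes, 21 passed in each of the 14; Lox and Atp13a4 did not under the replicate block and were left out by the median filter, Atp13a4 also without vehicle replicate 1, and Prg4 without DB2313 replicate 3. Of the lists, 6 passed; 11 did with an offset of 32, 12 with a trended and robust prior, 0 with an estimated correlation, and 3 to 8 with 1 array left out, the 3 without vehicle replicate 2. The lists of G2 and mitosis, heat shock, inflammation, cytokine receptors and histones passed with both the offset and the trended prior, glycolysis with the trended prior and the replicate block, and B lymphoid markers and histones with genes below the median signal left out. That filter left 3 of 18 B lymphoid markers and moved their mean from 0.11 to 0.64; it left 19 of 44 receptors (-0.17 to -0.39) and 20 of 43 macrophage markers (-0.10 to -0.17), and the offset moved that of the megakaryocyte list from -0.13 to -0.08. The ribosome biogenesis list passed under every alternative run but the estimated correlation. The real grouping of the arrays gave 401 genes and the highest of the other 9 splits 0, by limma; for lists these were 6 and 3. Only 1 of the 10 splits, the real one, reached these values in each case, and 10 splits are too few for a share under 0.05. Camera at the preset correlation passed 1, 2, 2, 2, 0, 3, 2, 2 and 0 lists in the other 9. These 9 mix both groups and keep part of their difference, so gene and list counts cannot gauge false calls. Probe set background was not measured here, which limits what can be said of dim genes.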

Other observations

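The tests on Serpinb9e, on the innate immune genes and on the level of the metabolic genes were chosen after the results were seen. Those on gene length, chromosomal neighbours and the splits of the arrays were set beforehand. The PPARgamma target list was drawn up after some genes had been seen to fall, but before the values of its members were looked at.

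Several metabolic genes fell with DB2313. They were chosen after their values were seen, because they fell, and no list or enrichment was tested with them. Beside Pparg, Me1 and Xdh these were Lpl, the lipase that takes up fatty acids from lipoproteins (log2 fold change -0.94), Dgat1 (-0.76), Dgat2 (-0.72) and Mogat2 (-0.70), which esterify glycerides, and Abhd5 (-0.78), the co-activator of triglyceride lipase. Fbp1, the gluconeogenic bisphosphatase, had -1.28, falling from 5.40 ± 0.09 to 4.12 ± 0.18 (SD, n = 3). All 9 passed in limma, also after quantile normalization, after median centring, with the replicate block and with each array left out. Among secreted and surface proteins, also chosen after their values were seen, Tslp (0.95), Igfbp7 (0.87), Cd274, encoding the checkpoint ligand PD-L1 (0.68), and Alcam (0.64) rose. Inhba, an activin subunit (-0.87), Hpse, encoding heparanase (-0.84), and Cd200r1 (-0.99) fell. These 7 also passed in each of those settings. Ugdh (-0.77), looked at too, passed in all of them, but some others looked at did not. Lgals9 (0.76), Lair1 (0.85) and Tgm2 (-0.88) passed in 4, 4 and 2 of the 6 settings with 1 array left out. Rgs2 (-0.83) and Cd200r4 (-0.65) passed in 4 and 2 of these 6. The 7 therefore do not stand for all such genes. Lpl and Hpse each have another, dimmer row, with -0.13 and -0.12.

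The rise of Serpinb9e began among the dimmest signals. Hybridisation of transcripts of Serpinb9, Serpinb9b or Serpinb9f to its probe set is argued against as the whole cause, provided their own probe sets respond. The largest rise among these, that of Serpinb9f, was 1.03 (SE 0.116) against 6.51. Their vehicle signals, 4.92, 4.88 and 4.75, lay below the median of all genes, 5.17, and background was not measured. Such hybridisation stays open for Serpinb9c, Serpinb9d and Serpinb9g, of which none rose by more than 0.19. Their signals lay in the lowest 25% of genes, where a probe set can respond too little to show a rise. Probe sequences were not compared. The 20 nearest genes had a median log2 fold change of 0.068, the 97.8th percentile of 21709 such windows, so a weak effect over the neighbourhood may exist. Of these 20 only Serpinb9f passed, also after quantile normalization and median centring, and many of them are Serpinb relatives whose probes could pick up Serpinb9e transcripts. A response of Serpinb9e itself to DB2313 stays open as a hypothesis.

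Of 120 measured genes on the macrophage, granule and receptor lists, 15 passed, 12 lower and 3 higher. The loss of a minority of mature myeloid cells would lower their genes together, and 1 higher gene at most was allowed. Clec7a, Anxa1 and Cybb, 3 genes, were higher. That limit was set after these genes had been seen, so the count cannot decide. Cybb and Anxa1 come from the granule list, which also holds genes of neutrophil precursors, and did not pass in several settings with 1 array left out. Named outside the rule, Lyz2 (log2 fold change -0.13), Itgam (-0.27), Irf8 (-0.13) and Kit (0.10) did not pass in limma. Ctss (-0.17) and Adgre1 (-0.09) did not pass either, at dim vehicle signals of 3.78 and 3.37. These few markers do not decide the question, so such a loss stays open. Of these genes 13 passed after quantile normalization and 16 after median centring. The deposited arrays already had nearly equal quartiles, and neither setting moved a passing member by more than 0.0186. A difference in overall signal was therefore not tested. A shift between myeloid states or a direct effect of DB2313 on these genes may account for the pattern and was not tested.

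The fall of Pparg with other metabolic genes could reflect a lower output of PPARgamma, which stays open. A list of 36 target genes, fixed before their values were looked at, left out Lpl and other genes already seen to fall, so it cannot exclude this. In it 34 were measured, with a mean log2 fold change of -0.02 and a camera p of 0.390, or p = 0.466 with an estimated correlation. Fabp5 (-0.35) and Plin2 (-0.45) fell and 0 rose, but both lost their calls when any 1 array was left out. All 9 metabolic genes named above had a vehicle mean above the median of all genes, 5.17, which tests nothing about genes near the floor, since the 9 were picked for their fall.

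Across 22139 genes, log2 fold change and genomic length had a Spearman's rho of 0.0030. Pairs of neighbouring tested genes that both passed in the same direction numbered 14, against a mean of 3.69 and a 95th percentile of 7 in 10000 random placements, none of which reached 14 (permutation p = 0.0001, the smallest these can give). The placements drew from all 22126 placed genes whatever their signal. Of the 401 genes past the threshold, 373 lay above the median signal. The permutation p therefore does not allow for neighbours that have like signal, and cannot tell that from a shared change. Chosen after their values were seen, these pairs include the related genes Dgat2 and Mogat2, Cd200r1 and Cd200r4, and Clec7a and Olr1, as well as Tmem156 (1.07) with Klhl5 (0.59) and H13 (0.50) with Mcts2 (0.88). Cd200r4 did not pass under the replicate block (adjusted p = 0.0897) and passed in 2 of the 6 settings with 1 array left out. H13 has another, dimmer row with 0.05. The related genes Serpinb9e and Serpinb9f, and Rnf130 with the microRNA Mir340, are also among the 14. Overlapping or related neighbours can share probe sequence and need not be independent, and neither point was examined.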
